A study of Danio rerio and Mus musculus with 14 samples.

How the data were processed

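Tomo-seq measures gene expression along 1 axis of a tissue. A frozen block is sectioned in order, the RNA of each section receives its own barcode, and the barcoded sections are sequenced together. The series holds 14 injured adult hearts, 5 from mouse and 9 from zebrafish. Mouse hearts were taken 3 days (1 heart), 7 days (2 hearts) and 14 days (2 hearts) after permanent ligation of the left anterior descending coronary artery, in animals carrying an Nppb:Katuschka transgene. Zebrafish hearts were taken 3, 7 and 14 days after cryoinjury of wildtype animals, with 3 hearts at each time. Per the labels, mouse sections were 20 µm thick with 80 µm of tissue passed over between them, every zebrafish section was used, and both ran from the injured area towards the remote myocardium.

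Per the labels' protocols, RNA was extracted with TRIzol and barcoded and amplified by CEL-seq, which reads the end of polyadenylated transcripts next to the poly(A) tail. The submitters' processing notes name BWA 0.6.2 and the mouse build GRCm38 for every sample, with no role given. The zebrafish build, the annotation, and whether reads were collapsed by molecular identifier are not given in the sources used here. The authors deposited, for each heart, whole-number counts per gene in 96 barcode columns, not normalized. Spike-in counts were left out of library sizes and tests, and made up at most 0.637% of the counts of a mouse heart and 0.814% of those of a zebrafish heart. Mouse genes carry symbols, and 10406 of the 10985 tested symbols (94.7%) were found in GENCODE M21, whose GRCm38 coordinates are printed. Zebrafish genes carry Ensembl identifiers, which the files do not pair with names, so at most 2 identifiers per direction are printed, gene lists were not tested in zebrafish, and the comparison of homologous genes between the species is not analysed here.

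A barcode column was kept as a section when its total reached 10% of the 90th percentile of the heart's column totals and at least 1000 counts. This kept 33 to 47 sections per mouse heart (208 in all) and 28 to 45 per zebrafish heart (318 in all), holding at least 97.7% of each heart's counts. Heart totals ran from 7276555 to 13753257 counts in mouse and from 1226081 to 12714932 in zebrafish. A floor of 3 counts in a heart's kept sections corresponded to 0.220 to 0.412 counts per 1e6 counts (CPM) in mouse and 0.238 to 2.46 CPM in zebrafish, and such floors cover counting error only. Neighbouring sections were compared by the mean correlation of log2(CPM + 10) over the 500 most variable genes, against 9999 shuffles of the section order in a 1-sided permutation test.

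The heart, and not the section, was the replicate. Each heart was divided into 3 runs of neighbouring sections, and counts were summed per heart and run. In mouse, the runs were the least-squares solution, with at least 4 sections per run, on 3 standardised scores. These were an injury score (Col1a1, Col1a2, Col3a1, Fn1, Postn, Sparc, Timp1, Spp1, Lyz2), a border score (Nppa, Nppb, Ankrd1, Mustn1, Xirp2) and a cardiomyocyte score (Myh6, Tnni3, Tnnt2, Atp2a2, Pln, Ckm, Mb, Cox6a2, Fabp3, Tcap), each from markers with a mean of at least 10 CPM in that heart. The outer run with the higher injury minus cardiomyocyte score was the injury segment, the other outer run the remote segment and the middle run the border segment. These 24 markers were fitted and counted in the adjustment of p-values but left out of all calls, lists and named genes, but genes expressed together with them differ between segments partly by construction. In zebrafish the same division was planned on markers and could not be made without gene names. The division named second beforehand took its place, with runs found on the first 3 principal components of the 500 most variable genes. These genes were not left out of the zebrafish calls, so genes that vary along a heart differ between its segments partly by construction. Zebrafish runs are called first, middle and last by barcode number, and that the first lies at the injured end rests on the labels' sectioning direction, not on markers.

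Summed counts were tested with limma 3.58.1 (voom) in R 4.3.3. Library sizes were scaled by the trimmed mean of M values (30% of M and 5% of A trimmed), computed by own code. A gene was kept when it reached the CPM of 10 counts at the median library in at least as many libraries as there were hearts, with at least 15 counts in all, which left 10985 mouse and 6696 zebrafish genes. Heart was a term of every model, so segments were compared within animals, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences between days were tested as interactions of segment and day. The quasi-likelihood count model chosen before the data were examined, and a further count model named beside it, were not fitted. The automated check of units could not read these tab-separated tables, so the values were not registered there as counts, and limma-voom was chosen instead after the values had been seen to be whole numbers. Data handling and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

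Segment markers, gene lists, segment definitions, the filter and the rule for named genes were fixed before the data were examined. The rule takes, per segment comparison, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 5 and 1 sign in all hearts or all but 1, up to 4 members of each list with the smallest p, the 5 highest and 5 lowest per day comparison, and Hmga1 and Hmga2. In mouse, 28 lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. They cover sarcomere, fetal cardiac and stress genes, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, cell cycle, ribosome biogenesis, translation, high mobility group and chromatin, hypoxia, heat shock and unfolded protein response, immediate early genes, extracellular matrix, fibroblast, macrophage, neutrophil, lymphocyte, interferon and inflammatory signalling, endothelium, epicardium, smooth muscle and pericyte, atrium, erythrocyte, thrombocyte and coagulation, regeneration signalling, cardiac transcription factors, and calcium handling and ion channels. Values per heart are log2 differences, and means are given with the SD over hearts or, for fitted fold changes, the standard error (SE).

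The fit was tested on simulated counts with 200 genes changed by known amounts and the spread set to each gene's residual variance after segment effects. The changed genes were drawn from those with a mean log2 CPM of at least 5, so recovery of genes with lower levels was not tested. The simulation began from counts already summed per segment, so it did not test the division of hearts into segments or false calls that the division may cause. Of genes changed 2-fold and 4-fold, 72% and 98% were recovered in the mouse border comparison (10818 genes, 17 false calls), 74% and 96% in the mouse injury comparison (10792 genes, 11 false calls), 49% and 94% in the zebrafish middle comparison (6477 genes, 22 false calls) and 26% and 83% in the zebrafish first comparison (6498 genes, 7 false calls). Between days, the recovered shares at 2-fold and 4-fold were 0% and 8% for the mouse border (10816 genes), 0% and 0% for the mouse injury segment (10763 genes), 0% and 7% for the zebrafish middle segment, day 7 against day 3 (6531 genes), and 0% and 0% for the zebrafish first segment, day 14 against day 3 (6521 genes).

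Alternatives were median-of-ratios size factors, no filter on low counts, 3 equal runs by position, principal-component segments (mouse), 1 boundary with a border of 15% of the sections on its remote side (mouse), sections kept from 25% of the 90th percentile, no heart term, a replicate block, each heart left out in turn, segments thinned to 1 depth per heart, zebrafish columns 1 to 48 only, and limma-trend on log2(CPM + 1) and log2(CPM + 10).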

Results

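The series asked how the response to heart injury differs between mouse, whose adult heart scars, and zebrafish, whose adult heart regenerates, and its title names Hmga1. Expression was measured in ordered sections of 14 injured hearts. No uninjured heart was measured, so position along a normal heart and the effect of injury cannot be told apart in either species. In mouse there was 1 heart at 3 days after ligation of a coronary artery, with 9097041 counts. There were 2 hearts at 7 days (11331843 and 13753257 counts) and 2 at 14 days (7276555 and 10220342 counts). Zebrafish hearts were studied after cryoinjury, a local freezing of the ventricle. They held 2542206, 2009471 and 1226081 counts at 3 days, 12714932, 12058158 and 8802502 at 7 days, and 5655893, 3707152 and 6782442 at 14 days. The hearts are taken as separate animals, as the labels number them within each group.

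Neighbouring sections were more alike than sections in shuffled order in every heart, weakly so in zebrafish 7 dpi heart 2. The mean correlation of neighbouring sections ran from 0.297 to 0.705 in the 5 mouse hearts and from 0.0647 to 0.582 in the 9 zebrafish hearts. Each exceeded all shuffled orders (permutation p = 0.0001, the smallest the shuffles can give). In all 5 mouse hearts the markers placed the injury at the low-numbered end. Mouse injury segments held 6 to 15 sections and 632213 to 3023896 counts, border segments 7 to 21 sections and 2788633 to 5084407 counts, and remote segments 14 to 27 sections and 2505863 to 6924433 counts. The border segments differed in make-up between hearts. In the day 3 heart the injury score was 0.840 in the injury, 0.601 in the border and -1.26 in the remote segment. In 14 dpi heart 2 it was 1.21, -0.208 and -0.976.

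**Figure D1:**
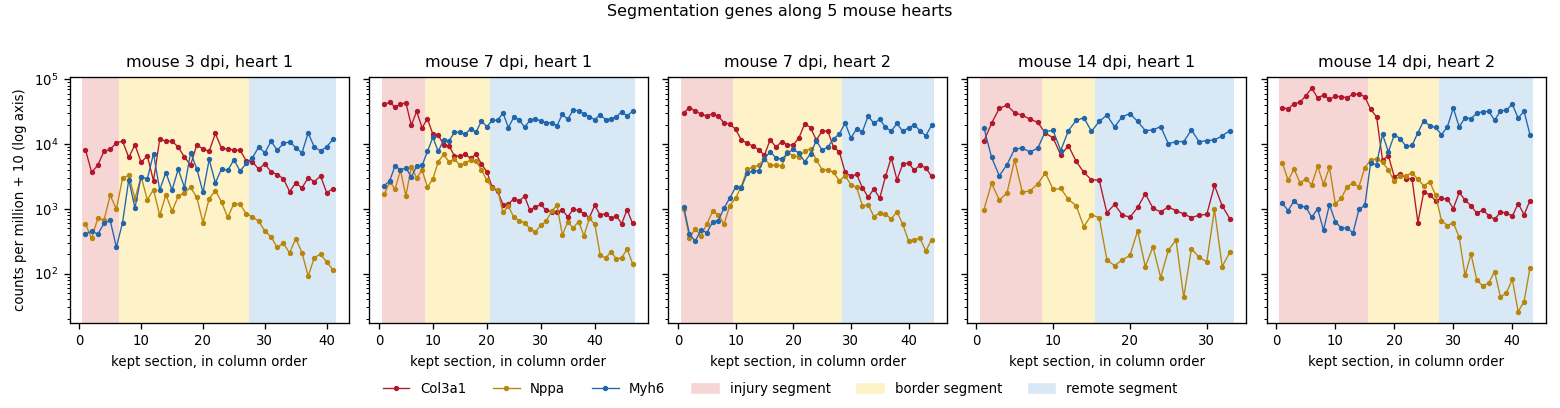
CPM + 10 (log axis) of Col3a1, Nppa and Myh6, 3 of the genes that define the segments, against the position of each kept section in the 5 mouse hearts, 1 panel per heart; shading marks the injury, border and remote segments. Because these genes define the segments, the panels show where the boundaries fell, with 33 to 47 sections per heart.

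The first comparison asked which genes differ between the border of the mouse injury and the remote myocardium of the same hearts. Without uninjured hearts, differences that run along a normal heart are part of this comparison. Genes of the extracellular matrix and of macrophages were higher in the border, and genes of mitochondrial energy metabolism were lower. These group calls held at a preset correlation only (camera adjusted p = 0.165 to 0.248 with an estimated correlation). The segments were cut on injury and cardiomyocyte markers, so genes expressed together with these differ between segments partly by construction. Among called genes with a mean log2 CPM of at least 5, the largest increase was that of Dkk3, a secreted protein of the Dickkopf family (log2 fold change 3.93 ± 0.47 SE, n = 5 hearts, limma adjusted p = 4.07e-05). Its level was 8.70 ± 4.83 CPM (SD) in the remote and 109 ± 71.7 CPM in the border segment, and it was higher in 5 of 5 hearts. Cilp, a cartilage matrix protein, was higher by 3.88 ± 0.43 (limma adjusted p = 2.93e-05). Dgat2, an enzyme of triglyceride synthesis, fell by 1.54 on the log2 scale (SE 0.25, limma adjusted p = 0.000483), from 401 ± 91.6 CPM (SD) to 146 CPM (SD 60). It was lower in 5 of 5 hearts.

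In all, 1069 genes were higher and 1178 lower in the border (limma-voom, 10961 genes after the 24 markers were left out). The 8 named increases also included Mfap4 (2.97), Comp (2.93), Col5a2 (2.70), Itgbl1 (2.58), Mfap5 (2.53) and elastin, Eln (2.49), most of which encode matrix or matrix-binding proteins. Comp and Eln were higher in 4 of 5 hearts, with log2 differences of -1.33 and -0.22 in the day 3 heart. The named decreases were Gm5595 (-1.60), Dgat2, Rpl3l (-1.53), a ribosomal protein paralog of striated muscle, Kif3a (-1.49), Ttll1 (-1.47), Dhrs7c (-1.38), Fitm1 (-1.35) and Hopx (-1.33), each lower in 5 of 5 hearts. Gm5595 is a predicted gene, and its reads could be split with similar loci. Dkk3 lies on chromosome 7 (112116017 to 112159057, minus strand), Cilp on chromosome 9 (65265180 to 65280605, plus strand), Dgat2 on chromosome 7 (99153658 to 99182719, minus strand) and Rpl3l on chromosome 17 (24727820 to 24736143, plus strand) of GRCm38.

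Of 46 tested extracellular matrix genes, 41 were higher and 0 lower in the border (42 and 0 adjusted over the list alone), with a median log2 fold change of 1.55. Col5a1 (2.05 ± 0.18 SE) and Tnc, the matrix glycoprotein tenascin C (3.04 ± 0.35), were among them, and the list was called up (camera adjusted p = 5.07e-31, adjusted p = 0.165 with an estimated correlation). Of 24 macrophage genes, 21 were higher and 0 lower (22 and 0 adjusted over the list alone; median 1.19), among them the lysosomal protease Ctss (1.69) and the galectin Lgals3 (2.42). The list was called up (adjusted p = 4.02e-16, adjusted p = 0.165 with an estimated correlation). Of 19 fibroblast genes, 10 were higher and 0 lower (11 and 1 adjusted over the list alone; median 0.87), with Cthrc1 at 4.73 ± 0.59 (SE). The list was called up (adjusted p = 9.91e-07, adjusted p = 0.246 with an estimated correlation).

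Cell cycle genes were also higher in the border, 18 of 40 (21 adjusted over the list alone) with 0 lower, among them Top2a (1.27 ± 0.20 SE), which untangles DNA during replication and mitosis, and the mitotic kinases Cdk1 (1.64) and Plk1 (1.94). The list median was 0.88, at 1.52 in the day 3 heart, 0.72 at day 7 and 0.22 at day 14 (camera adjusted p = 1.43e-10, adjusted p = 0.246 with an estimated correlation). Of 16 fetal cardiac and stress genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.80). The stress cytokine Gdf15 was higher by 2.16 ± 0.38 (SE) and Ctgf by 1.72 ± 0.29, while Fhl2, a protein that binds titin, fell by 1.24 (list adjusted p = 0.000423, adjusted p = 0.199 with an estimated correlation). Of 19 interferon and inflammatory genes, 4 were higher and 0 lower (4 and 0 adjusted over the list alone; median 0.21), with the chemokine Ccl2 at 2.02 (list adjusted p = 0.0341, adjusted p = 0.248 with an estimated correlation, adjusted p = 0.391 without the day 3 heart). This list was also not called with 3 equal runs (adjusted p = 0.137), principal-component segments (0.0601), a 15% border (0.0629), thinning (0.211, median 0.05) or limma-trend (0.121 and 0.117).

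Lists of oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation were lower in the border. Of 39 oxidative phosphorylation genes, 37 were lower and 0 higher (39 and 0 adjusted over the list alone; median -0.82), such as the complex III subunit Uqcrc1 (-1.01 ± 0.19 SE). The list was called down (camera adjusted p = 5.93e-18, adjusted p = 0.248 with an estimated correlation). Of 17 tricarboxylic acid cycle genes, 16 were lower (17 adjusted over the list alone; median -0.83), such as Ogdh (-0.99). Of 23 fatty acid oxidation genes, 22 were lower (22 adjusted over the list alone; median -1.03), such as Eci1 (-1.26). Both lists were called down (adjusted p = 1.80e-10 and 2.03e-16; adjusted p = 0.246 for each with an estimated correlation). Of 22 genes of calcium handling and ion channels, 11 were lower and 0 higher (15 and 0 adjusted over the list alone; median -0.56), including the calcium release channel Ryr2 (-1.21 ± 0.16 SE) and the L-type channel Cacna1c (-1.18) (list adjusted p = 3.21e-08, adjusted p = 0.246 with an estimated correlation).

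Of 20 sarcomere genes, 4 were lower and 0 higher in the border (9 and 0 adjusted over the list alone; median -0.52), among them Ldb3 (-0.96) and Myl2 (-1.03) (camera adjusted p = 0.000638, adjusted p = 0.487 with an estimated correlation). Of 20 cardiac transcription factors, 8 were lower and 1 higher (10 and 1 adjusted over the list alone; median -0.45). The 1 that was higher was Runx1 (2.07 ± 0.28 SE, from 6.49 ± 3.99 to 25.2 ± 10.1 CPM, SD; chromosome 16, 92601466 to 92826149, minus strand), and Klf15 (-1.34) was among those lower (list adjusted p = 0.00165, adjusted p = 0.246 with an estimated correlation, adjusted p = 0.204 and median -0.13 with a 15% border). Of 6 erythrocyte genes, 4 were lower (6 adjusted over the list alone; median -0.97), such as Hba-a1 (-1.24), a globin that shares reads with near-identical copies (list adjusted p = 0.000423, adjusted p = 0.246 with an estimated correlation, adjusted p = 0.202 and median -0.31 with a 15% border).

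The remaining 15 lists were not called in the border. Their counts of higher and lower genes, with the counts adjusted over the list alone following, were 2 and 4 of 19 for glycolysis (2 and 4), 1 and 1 of 25 for ribosome biogenesis (0 and 0), 2 and 0 of 32 for translation (0 and 0), 1 and 1 of 25 for high mobility group and chromatin genes (1 and 0), and 1 and 5 of 17 for hypoxia targets (3 and 5). They were 3 and 1 of 23 for heat shock and unfolded protein genes (3 and 1), 3 and 0 of 15 for immediate early genes (3 and 0), 1 and 1 of 9 for neutrophil genes (1 and 1), 1 and 0 of 3 for lymphocyte genes (1 and 0), and 1 and 2 of 23 for endothelium (1 and 1). They were 2 and 1 of 9 for epicardium (3 and 1), 3 and 1 of 12 for smooth muscle and pericyte (3 and 1), 1 and 1 of 8 for atrium (1 and 1), 1 and 0 of 7 for thrombocyte and coagulation (1 and 0), and 7 and 3 of 34 for regeneration signalling (8 and 4). Vegfa, the angiogenic growth factor, fell by 0.77 on the log2 scale, while the haem oxygenase Hmox1 was higher by 1.14.

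The border count depended on how the segments were drawn. It was 28 with a border of the 15% of sections on the remote side of 1 boundary, 276 with 3 equal runs and 1305 with principal-component segments. In the day 3 heart the 15% border was columns 35 to 40, inside the main remote segment (35 to 48). In 7 dpi heart 2 it was columns 31 to 38, where the main remote segment began at 33. Most or all of the main border of these 2 hearts then joined the injury segment, so the fall to 28 does not test border placement alone. With 3 equal runs, the border was columns 18 to 32 in 7 dpi heart 1, where the main remote segment began at 22. In 14 dpi heart 1 it was 12 to 22, with main remote from 16. The principal-component remote segment of 14 dpi heart 1 was columns 30 to 33, with 173718 counts. The counts of 276 and 1305 thus also mix border placement with changes of the other segments. Of the genes named by rule in the border or its lists, 92 of 103 lost or reversed their call with a 15% border, Lgals3 (1.08, adjusted p = 0.0571) among them. The 11 kept were Dkk3, Cilp, Mfap4, Col5a2, Mfap5, Ctgf, Top2a, Col5a1, Col8a1, Clu and Cacna1c. The call was lost in 69 of 104 with 3 equal runs and 61 of 104 without the heart term. With 3 equal runs, Dgat2 (-0.96), Rpl3l (-1.01), Kif3a (-1.20), Dhrs7c (-1.02), Fitm1 (-1.02), Hopx (-0.82) and Eln (1.87) were no longer called. The count was 367 without the heart term, 1304 with segments thinned to 1 depth, 1181 and 1323 with limma-trend (Comp no longer called, at 2.00 and 1.48), and 1264 and 1186 without 7 dpi heart 1 or 2.

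**Figure D2:**
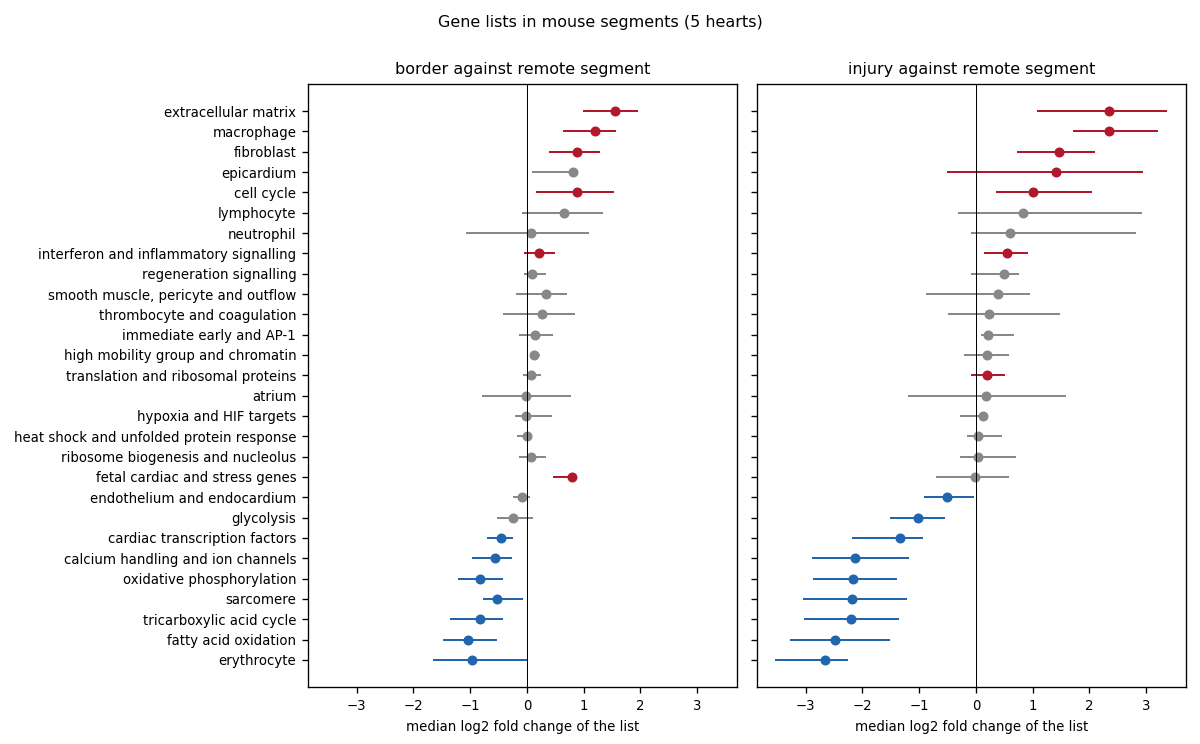
Median log2 fold change of each of 28 fixed gene lists in the border (left) and injury (right) segments against the remote segment of 5 mouse hearts; points are fitted medians, bars run from the lowest to the highest heart's median, and red or blue marks lists called up or down by camera at a preset correlation. With an estimated correlation 0 lists were called. The extracellular matrix list has medians of 1.55 and 2.34 and the fatty acid oxidation list -1.03 and -2.49.

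The second comparison set the injury segment against the remote segment. Matrix and macrophage genes were higher there too, and contractile, ion channel and mitochondrial genes were lower. These group calls also held at a preset correlation only (camera adjusted p = 0.138 or more with an estimated correlation), and they too follow in part from how the segments were cut. Among called genes with a mean log2 CPM of at least 5, Dkk3 had the largest increase (5.08 ± 0.47 SE, n = 5 hearts; limma adjusted p = 1.22e-07), from 8.70 ± 4.83 to 306 ± 337 CPM (SD). Lgals3, a galectin of activated macrophages, was higher by 4.13 ± 0.29 (limma adjusted p = 1.40e-08; chromosome 14, 47367751 to 47386160, plus strand). Dgat2 fell by 4.11 on the log2 scale (SE 0.34, limma adjusted p = 3.81e-08), from 401 ± 91.6 to 28.3 ± 25.3 CPM (SD).

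In all, 2607 genes were higher and 2708 lower in the injury segment. The named increases also held Comp (4.91), Mfap4 (4.30), Cilp (4.0), Ms4a7 (3.89), Col5a2 (3.82) and Col14a1 (3.79). In the single day 3 heart, Dkk3 and Comp had log2 differences of -0.77 and -1.15, against 6.62 and 7.07 at day 14. The named decreases were Dgat2, Rpl3l (-4.10), Lrtm1 (-3.88), the mitochondrial fission protein Mtfp1 (-3.79), D830015G02Rik (-3.78), Fndc5 (-3.77), the precursor of irisin, Hopx (-3.73) and Dhrs7c (-3.70), each lower in 5 of 5 hearts.

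Of 20 sarcomere genes, 19 were lower and 0 higher (19 and 0 adjusted over the list alone; median -2.19), with the ventricular light chain Myl2 at -3.29 ± 0.29 (SE) (camera adjusted p = 7.83e-11, adjusted p = 0.201 with an estimated correlation). All 39 oxidative phosphorylation genes (39 adjusted over the list alone; median -2.16), all 17 tricarboxylic acid cycle genes (17 adjusted over the list alone; median -2.19) and 22 of 23 fatty acid oxidation genes (22 adjusted over the list alone; median -2.49) were lower. These 3 lists were called down (adjusted p = 2.78e-25, 2.84e-13 and 1.12e-16; adjusted p = 0.193 for each with an estimated correlation). Of 22 calcium handling and ion channel genes, 20 were lower and 1 higher (20 and 1 adjusted over the list alone; median -2.12), with Ryr2 at -3.09 ± 0.18 (SE) (list adjusted p = 5.14e-11, adjusted p = 0.193 with an estimated correlation). Of 19 glycolysis genes, 12 were lower, such as the muscle enolase Eno3 (-3.66), and 4 higher (12 and 4 adjusted over the list alone; median -1.02) (list adjusted p = 0.00642, adjusted p = 0.464 with an estimated correlation).

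Of 46 extracellular matrix genes, 42 were higher and 0 lower (43 and 0 adjusted over the list alone; median 2.34), with a median of 1.1 in the day 3 heart and 2.93 at day 14 (camera adjusted p = 6.14e-20, adjusted p = 0.193 with an estimated correlation). Of 24 macrophage genes, 23 were higher and 1 lower (23 and 1 adjusted over the list alone; median 2.34), such as Ctss (3.52 ± 0.20 SE) (list adjusted p = 5.78e-15, adjusted p = 0.138 with an estimated correlation). Of 19 fibroblast genes, 14 were higher and 0 lower (15 and 1 adjusted over the list alone; median 1.46), such as S100a4 (3.15) (list adjusted p = 3.73e-07, adjusted p = 0.193 with an estimated correlation). Of 40 cell cycle genes, 28 were higher and 2 lower (28 and 2 adjusted over the list alone; median 1.00), such as Top2a (1.66) and Birc5 (1.94) (list adjusted p = 1.60e-05, adjusted p = 0.359 with an estimated correlation).

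Of 19 interferon and inflammatory genes, 8 were higher and 1 lower (8 and 1 adjusted over the list alone; median 0.56), with Ccl2 at 3.07 ± 0.51 (SE), in 4 of 5 hearts, not called by limma-trend or without the day 3 heart (camera adjusted p = 0.0180, adjusted p = 0.219 with an estimated correlation, adjusted p = 0.0658 without the day 3 heart). Of 32 translation genes, 10 were higher and 0 lower (7 and 0 adjusted over the list alone; median 0.19) (adjusted p = 0.0239, adjusted p = 0.677 with an estimated correlation, adjusted p = 0.167 without the day 3 heart, adjusted p = 0.242 with no filter). Of 9 epicardial genes, 6 were higher and 0 lower (6 and 1 adjusted over the list alone; median 1.42), with Krt18 at 4.19 ± 0.61 (SE) (list adjusted p = 0.0335, adjusted p = 0.293 with an estimated correlation, adjusted p = 0.0745 without 7 dpi heart 1). Of 23 endothelial genes, 11 were lower and 2 higher (11 and 2 adjusted over the list alone; median -0.50), with the receptor Kdr at -2.12 ± 0.21 (SE) (list adjusted p = 0.0148, adjusted p = 0.293 with an estimated correlation, adjusted p = 0.0863 and median -0.26 with a 15% border). All 6 erythrocyte genes were lower (6 adjusted over the list alone; median -2.66; list adjusted p = 0.000825, adjusted p = 0.251 with an estimated correlation). Of 20 cardiac transcription factors, 12 were lower, such as Nkx2-5 (-2.01), and 1 higher, Runx1 at 3.41 ± 0.27 (SE) (13 and 1 adjusted over the list alone; median -1.33; list adjusted p = 0.00120, adjusted p = 0.193 with an estimated correlation).

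The other 12 lists were not called in the injury segment. Higher and lower genes, with the counts adjusted over the list alone following, were 6 and 4 of 16 for fetal cardiac and stress genes (6 and 4), 3 and 3 of 25 for ribosome biogenesis (2 and 3), 4 and 2 of 25 for high mobility group and chromatin genes (4 and 1), 4 and 6 of 17 for hypoxia targets (4 and 6), 8 and 5 of 23 for heat shock and unfolded protein genes (8 and 6), and 6 and 1 of 15 for immediate early genes (6 and 1). They were 4 and 1 of 9 for neutrophil genes (4 and 1), 1 and 0 of 3 for lymphocyte genes (1 and 0), 5 and 4 of 12 for smooth muscle and pericyte (5 and 4), 1 and 2 of 8 for atrium (1 and 2), 2 and 1 of 7 for thrombocyte and coagulation (2 and 1), and 14 and 8 of 34 for regeneration signalling (14 and 8). Among these, Fos was higher by 2.5 ± 0.30 (SE) and the contractile smooth muscle gene Cnn1 by 3.47 ± 0.39, while Fhl2 fell by 3.09 and Id1 by 1.23.

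**Figure D3:**
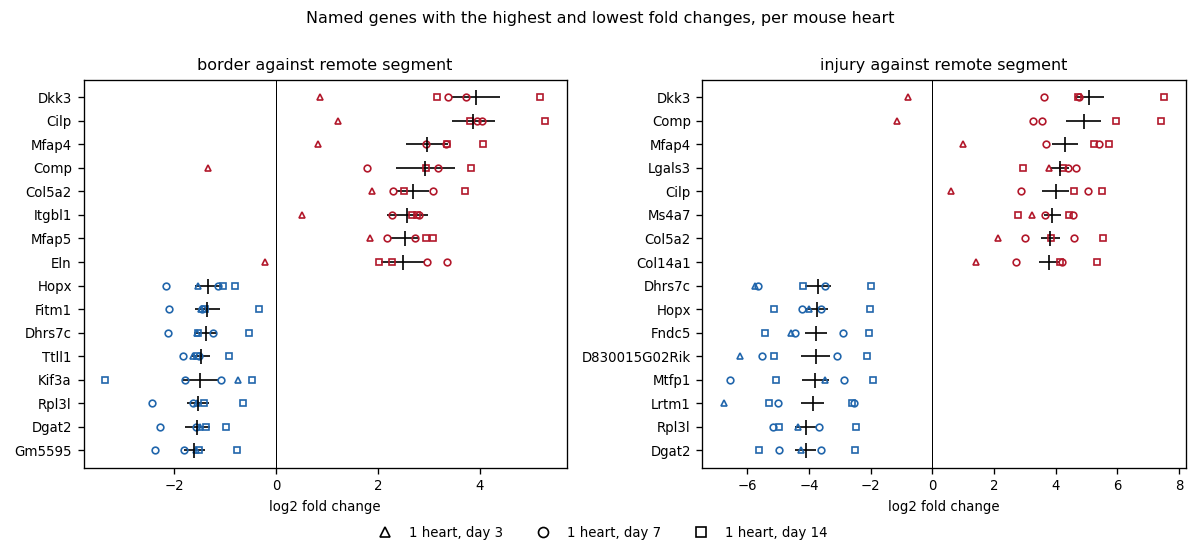
Log2 fold change of the named genes in the border (left) and injury (right) segments against the remote segment; open symbols are single hearts (triangles day 3, circles day 7, squares day 14), and vertical and horizontal bars mark the fitted value and its SE. Dkk3 stands at 3.93 and 5.08 in the fits, and its day 3 heart lies lowest in both panels.

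Genes that stood out in the border from both neighbours were few. Of the 2247 genes called between border and remote, 2102 (93.5%) had fitted border levels between those of the injury and remote segments. Rcan1, a regulator of calcineurin, was higher in the border than in both, by 0.79 ± 0.21 (SE) against remote and 0.89 ± 0.21 against injury (limma adjusted p = 0.0120 and 0.00493, 5 of 5 hearts; chromosome 16, 92391953 to 92470867, minus strand). It had 188 ± 43 CPM (SD) in the border, 109 ± 49.1 in the injury and 107 ± 16.8 in the remote segment. Synpo2l (1.40 against remote, 1.33 against injury), Gnao1 (0.62, 0.72) and 1700025G04Rik (0.46, 0.49) were the other genes higher than both, each in 4 of 5 hearts. Pygl, the liver form of glycogen phosphorylase, was lower than both (-0.73 against remote and -1.06 against injury, 5 of 5 hearts). So were Mup3 (-1.92, -1.77) in 5 of 5 hearts, and Cyp26b1 (-1.72, -1.56) and Fcna (-1.19, -1.67), each in 4 of 5. Synpo2l, Cyp26b1, Fcna and Mup3 had low mean log2 CPM (1.42, 2.61, 2.59 and 1.45). In the injury segment, the SD exceeded the mean for Synpo2l (3.21 ± 3.36 CPM), Fcna (14.6 ± 19.7) and Mup3 (7.44 ± 8.4). A floor of 3 counts there was 0.992 to 4.75 CPM. These 8 genes were named after their values were seen.

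Hmga1, the chromatin protein that the series title names, had almost no counts in the mouse hearts and was listed for 2 of the 5. It had 2 counts among the 51495063 in kept sections, 1 in each of 2 hearts, or 0.0388 CPM, below the floor of 3 counts in each heart (0.220 to 0.412 CPM). Hmga2 had 302 counts in 4 hearts (5.86 CPM over the kept sections of all 5), with log2 fold changes of -0.25 ± 0.51 (SE; limma adjusted p = 0.788) in the border and 0.13 ± 0.55 (adjusted p = 0.866) in the injury segment. Injury against remote levels were 18.8 against 6.50 and 14.9 against 7.56 CPM in the day 7 hearts. They were 2.11 against 10.4 and 0.590 against 0.697 CPM in the day 14 hearts, and the border of 14 dpi heart 1 held 66 of the counts. A pseudogene, Hmga2-ps1, that could share its reads had 314 counts. Hmga1 lies on chromosome 17 (27556497 to 27563674, plus strand) and Hmga2 on chromosome 10 (120361275 to 120476469, minus strand). Among related genes, Hmgn1 (0.82 ± 0.14, SE) and Hmgn3 (1.22 ± 0.25) were higher and Hmgb3 (-1.28 ± 0.23) lower in the injury segment.

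The next comparison asked whether the mouse segments changed between day 7 and day 14, with 2 hearts at each time. In the border, lists of energy metabolism were closer to remote levels at day 14. The cardiomyocyte score of the border was also higher at day 14 (0.229 and 0.480) than at day 7 (-0.223 and 0.0308). Each score was standardised within its heart and depends on that heart's share of injured sections, so it is not on 1 scale between hearts or days. The sarcomere list, not called, moved by 0.37 (camera adjusted p = 0.0583). No test separated the energy metabolism lists from this score. The differences in list medians were 0.42 for oxidative phosphorylation, 0.49 for the tricarboxylic acid cycle, 0.55 for fatty acid oxidation, 0.40 for glycolysis, 0.42 for calcium handling and 0.67 for erythrocyte genes, and these 6 were called up. The lists of cell cycle (-0.17), translation (-0.15), immediate early (-0.19), macrophage (-0.17) and lymphocyte genes (-0.64) were called down (limma camera adjusted p = 2.70e-05 to 0.0271 over these 11 lists, adjusted p = 0.776 for each with an estimated correlation). In the injury segment, fibroblast (0.94), extracellular matrix (0.59), atrium (1.03), regeneration signalling (0.37), cardiac transcription factor (0.52) and calcium handling lists (0.53) were called up and macrophage (-0.45), cell cycle (-0.34), epicardium (-0.83) and lymphocyte lists (-1.72) down. Their adjusted p ran from 5.74e-06 to 0.0254 (adjusted p = 0.202 to 0.583 with an estimated correlation). Each of these 11 border lists and 10 injury lists lost its call under at least 1 alternative or left-out heart. With a 15% border 7 border lists reversed, oxidative phosphorylation at -0.10 and fatty acid oxidation at -0.11 among them. In that setting the border of 7 dpi heart 2, 1 of the 2 day 7 hearts, was mostly main remote sections. Its cardiomyocyte score was 0.833, against 0.0308 in the main border. With 1 heart left out, the border medians ran from -0.62 to 0.12 for cell cycle, from -1.15 to -0.07 for lymphocyte and from 0.01 to 1.38 for erythrocyte genes. In the injury segment they ran from -0.85 to 0.10 for macrophage, from -1.45 to -0.05 for epicardium, from -0.20 to 0.96 for calcium handling and from 0.07 to 0.93 for extracellular matrix genes. The epicardium median was 0.17 with 3 equal runs. The fibroblast and extracellular matrix lists were not called without 14 dpi heart 2.

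No list held a gene past the threshold over all genes. Adjusted over the list alone, 2 erythrocyte genes and 1 endothelial gene were higher and 1 lymphocyte gene lower at day 14 in the border. In the injury segment, 1 fetal or stress, 2 extracellular matrix, 3 fibroblast, 2 endothelial and 3 atrial genes were higher, and 1 extracellular matrix, 1 lymphocyte and 1 epicardial gene lower. Limma-voom called 0 genes in the border (314 at an unadjusted p under 0.05) and 0 in the injury segment (512), and limma-trend called 0 in both. Of simulated 4-fold changes between days, in genes with a mean log2 CPM of at least 5, 8% were recovered in the border and 0% in the injury segment.

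In zebrafish, the first segment differed from the last by 534 genes that were higher and 815 that were lower (limma-voom, 6696 genes tested, 9 hearts). The segments were cut on the most variable genes of each heart, which stayed in the tests, so these calls follow in part from the cut. First segments held 24291 to 4321551 counts and last segments 213952 to 9417817, with fewer in the first segment of every heart. Depth thus runs along with this comparison. The gene ENSDARG00000088641 was higher by 2.46 ± 0.57 (SE, limma adjusted p = 0.00435) in 9 of 9 hearts, and ENSDARG00000010434 by 2.41 ± 0.56 (limma adjusted p = 0.00432) in 8 of 9. The gene ENSDARG00000087665 fell by 4.79 on the log2 scale (SE 0.75, limma adjusted p = 0.000330), from 672 ± 772 to 36.4 ± 36.8 CPM (SD), and ENSDARG00000077236 fell by 4.63 (SE 0.60, limma adjusted p = 0.000105), each in 8 of 9 hearts. The files do not pair these identifiers with names, and the injured end was not checked with markers. The count was 8800 with no filter, 838 with thinned segments, 717 without the heart term, 2097 with columns 1 to 48 only, 730 without 14 dpi heart 3, 782 without 14 dpi heart 1 and 827 without 7 dpi heart 1. Limma-trend called 128 higher and 1029 lower or 165 and 1006. With log2(CPM + 1), ENSDARG00000010434 was not called (1.55, adjusted p = 0.136).

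The middle and last segments of the zebrafish hearts differed by 1 gene, higher in the middle (limma-voom; 545 at an unadjusted p under 0.05), while limma-trend called 0. The last segments of day 3 hearts 1 and 2 lay in barcode columns 54 to 80 and 49 to 76, while the kept columns of each other heart ended by 48. The middle minus last differences of these 2 hearts had median Spearman correlations across genes, which are not independent replicates, of -0.43 and -0.35 with the other 7 hearts, and 0.60 with each other. With columns 1 to 48 only and segments found again, an alternative added after the values were seen, these correlations were 0.27 and 0.29. In that setting 262 genes were higher and 550 lower in the middle segment. Without these 2 hearts, also added afterwards, 79 genes were higher and 272 lower.

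**Figure D4:**
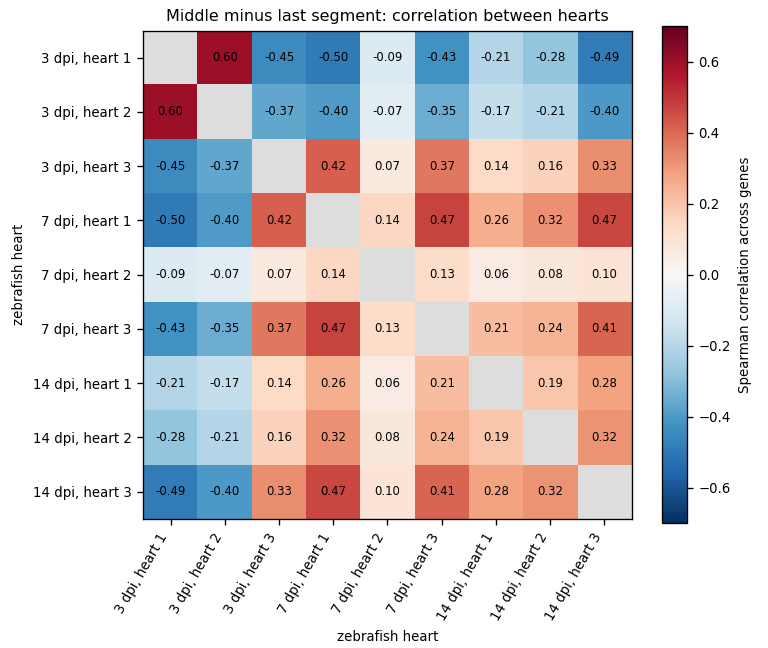
Spearman correlation across genes of the middle minus last log2 differences for each pair of 9 zebrafish hearts, with the value printed in each cell and red and blue for positive and negative. Day 3 hearts 1 and 2 correlate at 0.60 with each other and below 0 with each of the other 7 hearts.

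Day comparisons in zebrafish (3 hearts each) found few genes. In the middle against the last segment, limma-voom called 3 genes lower at day 7 than at day 3 (1163 at an unadjusted p under 0.05; 0 by limma-trend). It called 0 for day 14 against day 3 (743 unadjusted; 0 by limma-trend) and 0 for day 14 against day 7 (276 unadjusted; 0 by limma-trend). In the first against the last segment, it called 0 for day 7 against day 3 (546 unadjusted; 1 and 0 by limma-trend). It called 1 gene higher at day 14 than at day 3 (780 unadjusted; 42 and 102 by limma-trend), and 1 higher and 2 lower at day 14 than at day 7 (813 unadjusted; 0 by limma-trend). Without day 3 heart 3, the middle segment gave 788 genes for day 7 against day 3 and 480 for day 14 against day 3, and the first segment 35 and 148. With columns 1 to 48 only, the middle segment gave 0 genes for day 7 against day 3 (331 unadjusted), and the first segment 17 for day 14 against day 7.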

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

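The test of genes higher in the border than in both neighbours was written before its result was seen; the fetal and stress list, the splits, the thinning and the tests of the zebrafish day 3 hearts were chosen after the results were seen.

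Differences between days were tested as interactions. They gave 3 genes for the zebrafish middle segment, day 7 against day 3, 1 for the first segment, day 14 against day 3, and 3 for the first segment, day 14 against day 7. In mouse they gave 11 lists for the border and 10 lists for the injury segment, day 14 against day 7. Signal outside the sections used made up 2.27% of the counts of zebrafish 14 dpi heart 3, the share in columns below the section threshold. Spike-in counts made up 0.814% of the counts of zebrafish 7 dpi heart 2.

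The first pattern weighed was the 2247 genes called between mouse border and remote segments. Unequal depth of a heart's segments was argued against as the whole cause, since 56.3% of these genes were called in the same direction with segments thinned to 1 depth. A border segment that is only a mixture of injured and remote tissue stays open: it allows few genes beyond both neighbours, and 4 were higher than both where a true border state had been expected to give at least 20. The border markers Nppa, Nppb, Ankrd1, Mustn1 and Xirp2 had been left out of that count, so it cannot speak for them. The fetal and stress list had a median of 0.80 in the border, above 0 in 5 of 5 hearts, against -0.02 in the injury segment, but its median beyond the higher neighbour was above 0 in 1 of 5 hearts, which leaves the mixture open. A gradient of cell states along the tissue could give the same values, and noise in the remote segments, which the calls and the between class share, would raise the 93.5% lying between.

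The second pattern was that zebrafish day 3 hearts 1 and 2 ran against the other 7 hearts; unequal depth was argued against, since after thinning their middle minus last differences still had median correlations of -0.285 and -0.203 with the other 7 hearts. Day after injury was argued against as the whole cause, since day 3 heart 3 correlated at -0.446 and -0.366 with them. A reversed order of all sections was argued against: first minus last medians were -0.243 and -0.0567 with 3 equal runs, but 0.352 and 0.376 with columns 1 to 48 only. What remains is the last segment itself, drawn in these 2 hearts from columns above 48 that no other heart used: with columns 1 to 48 only, the middle minus last medians were 0.266 and 0.291. What the columns above 48 hold was not tested, and the kept columns of these 2 hearts had 0 in common, against at least 11 for the other pairs.

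In mouse, the 16 splits that swap segments within the 5 hearts are too few for a share under 0.05. For the 2247 border genes 1 gave as many, the real one, with 10 in the highest other, and for the 5315 genes of the injury segment 1 of 16 did, with 687 in the highest other. Markers had set the mouse segments and their order in every heart, so the real split leads partly by construction. For the 1349 genes of the zebrafish first segment, 2 of 100 splits gave as many, the real one among them. That share is under 0.05 and argues against chance alone. Such splits cannot separate position from depth, since the first segment held fewer counts than the last in every heart. The highest other split gave 1758. For the 1 gene of the middle segment, 9 of 100 splits gave as many, so chance cannot be excluded. Its highest other split gave 997 genes. The highest splits set day 3 hearts 1 and 2 against the other 7, which points to a structure of the samples, and without these 2 hearts the counts were 1904 and 351, and with columns 1 to 48 only 2097 and 812. The 10 splits of 6 hearts are too few for a share under 0.05 in the day comparisons. In the middle segment, 2 of 10 splits gave as many for day 7 against day 3 (real 3, highest other 835), 10 of 10 for day 14 against day 3 (real 0, highest other 101) and 10 of 10 for day 14 against day 7 (real 0, highest other 0). In the first segment, 10 of 10 did for day 7 against day 3 (real 0, highest other 53), 1 of 10 for day 14 against day 3 (real 1, highest other 0) and 2 of 10 for day 14 against day 7 (real 3, highest other 16).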

How the results depend on the processing

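Thinning, limma-trend, median-of-ratios factors, the replicate block in mouse, zebrafish columns 1 to 48 only and leaving out 2 zebrafish hearts together were chosen after the data were seen. Where a result moved, the cause was not tested, except that no filter tests more genes and fewer hearts leave fewer degrees of freedom. Counts of genes stayed within 1.5 times in 115 comparisons with an alternative and moved in 91. List medians kept direction and call in 652, lost the call alone in 127 and reversed in 17, by the sign of the median in 16 and by camera direction in 9 (8 by both). Counting the sign of the median as well as the camera direction was decided after the values were seen. Named genes did so in 2930, 436 and 1. Leaving a day with 1 heart assumes that it varies like the other groups. Not run were the count models planned first, zebrafish marker segments, their 1-boundary form, zebrafish lists and the species comparison with its alternatives. At this depth a gene under 0.220 to 0.412 CPM per heart falls below the floor of 3 counts, and why Hmga1 lay there was not tested.

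The mouse border count of 2247 was 276 with 3 equal runs, 1305 with unsupervised segments, 28 with 1 boundary and a 15% border, 1304 with thinning, 367 without the heart term, and 1181 and 1323 with limma-trend. The 15% border took in main remote sections in the day 3 heart and in 7 dpi heart 2. So did the border of 3 equal runs in other hearts, such as 7 dpi heart 1 and 14 dpi heart 1. Of the genes named in the border, 92 of 103 lost or reversed their call with a 15% border, 69 of 104 with 3 equal runs, 61 of 104 without the heart term and 5 to 29 of 104 with 1 heart left out; in the injury segment at most 4 did under any setting. Leaving out 1 heart gave 1186 to 2118, with 1264 without 7 dpi heart 1 and 1186 without 7 dpi heart 2. The injury count of 5315 stayed within 1.5 times under each alternative run, at 4476 to 5240 with 1 heart left out. Day 14 against day 7, the injury segment gave 1 gene with a 15% border and 0 to 4 with 1 heart left out, 4 without 14 dpi heart 1 and 2 without 14 dpi heart 2. The border gave 0 to 0.

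With an estimated correlation, 0 lists were called in the border and 0 in the injury segment, and 0 in each for day 14 against day 7. With a 15% border, the day 14 minus day 7 medians in the border reversed for oxidative phosphorylation (-0.10), tricarboxylic acid cycle (-0.10), fatty acid oxidation (-0.11), translation (0.0643), macrophage (0.0780), erythrocyte (-0.0212) and calcium handling (-0.0121), and Alas2 in the border was 0.12. The border cell cycle median was 0.0126 with thinning and 0.123 without 14 dpi heart 1, and that of immediate early genes was 0.0365 with unsupervised segments. In the injury segment, epicardium was 0.175 with 3 equal runs, where camera still called it down (adjusted p = 0.0370), and calcium handling was -0.0135 with 3 equal runs and -0.00924 with a 15% border. Macrophage was 0.103 without 7 dpi heart 1, and calcium handling -0.0143 without 7 dpi heart 2 and -0.202 without 14 dpi heart 1. The extracellular matrix list kept a positive median, 0.0720, without 14 dpi heart 2 and reversed by camera direction only. With 1 heart left out, the border medians ran from -0.619 to 0.123 for cell cycle, 0.209 to 0.585 for oxidative phosphorylation, 0.210 to 0.752 for the tricarboxylic acid cycle, 0.327 to 0.697 for fatty acid oxidation, 0.175 to 0.610 for glycolysis and 0.318 to 0.602 for calcium handling. They ran from -0.250 to -0.0311 for translation, -0.410 to -0.192 for immediate early genes, -0.576 to -0.121 for macrophage, -1.15 to -0.0693 for lymphocyte and 0.00728 to 1.38 for erythrocyte genes. In the injury segment they ran from -0.849 to 0.103 for macrophage, -0.684 to -0.326 for cell cycle, -3.26 to -0.841 for lymphocyte, -1.45 to -0.0456 for epicardium and -0.202 to 0.957 for calcium handling. They ran from 0.0720 to 0.928 for extracellular matrix, 0.430 to 1.26 for fibroblast, 0.602 to 1.3 for atrium, 0.283 to 0.450 for regeneration signalling and 0.264 to 0.534 for cardiac transcription factors. With a 15% border, cardiac transcription factors (adjusted p = 0.204), erythrocyte genes (0.202) and interferon genes (0.0629) in the border and endothelium (0.0863) in the injury segment were not called. The border interferon list was also lost with 3 equal runs, unsupervised segments, thinning, limma-trend and without the day 3 heart. In the injury segment, translation was lost with no filter (0.242), 3 equal runs (0.0564), no heart term (0.0554) and without 3 dpi heart 1 (0.167) or 7 dpi heart 1 (0.0835), interferon with no filter (0.0745), thinning (0.0948) and without 3 dpi heart 1 (0.0658), and epicardium with limma-trend on log2(CPM + 10) (0.0614) and without 7 dpi heart 1 (0.0745). Day 14 against day 7, the 11 border lists became 6 with 3 equal runs, 7 with unsupervised segments, 2 with a 15% border, 7 with thinning and 5 to 11 with 1 heart left out (6 without 7 dpi heart 2, 5 without 14 dpi heart 1). The 10 injury lists became 5 with 3 equal runs and 6 with a 15% border, and 10 to 13 with 1 heart left out.

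The zebrafish middle count of 1 was 0 with no filter, 0 with 3 equal runs, 0 with sections from 25%, 0 with thinning, 0 without the heart term and 0 and 0 with limma-trend, 351 without day 3 hearts 1 and 2, 812 with columns 1 to 48, and 0 to 4 with 1 heart left out (4 without 3 dpi heart 1, 3 without heart 2, 2 without 14 dpi heart 1, 0 without 3 dpi heart 3, any 7 dpi heart or 14 dpi hearts 2 or 3). The first count of 1349 was 8800 with no filter, 838 with thinning, 717 without the heart term, 2097 with columns 1 to 48 (96.3% of the 1349 called in the same direction) and 730 to 1692 with 1 heart left out (827 without 7 dpi heart 1, 782 without 14 dpi heart 1, 730 without 14 dpi heart 3). Limma-trend called 128 higher and 1029 lower, or 165 and 1006, against 534 and 815.

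For the middle segment, day 7 against day 3, the 3 genes became 9 with no filter, 0 with 3 equal runs, 0 with sections from 25%, 169 with thinning, 0 with columns 1 to 48, 0 and 0 with limma-trend, and 0 to 788 with 1 heart left out (788 without 3 dpi heart 3, 1 without 3 dpi heart 2 or 14 dpi heart 3, 0 without 3 dpi heart 1 or 14 dpi heart 2). Day 14 against day 3 gave 1 with thinning and 0 to 480 (480 without 3 dpi heart 3, 2 without 7 dpi heart 2). Day 14 against day 7 gave 0 to 1 (1 without 14 dpi heart 3).

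For the first segment, day 7 against day 3 gave 10 with no filter, 1 with 3 equal runs, 21 with thinning, 1 with limma-trend on log2(CPM + 1), and 0 to 35 with 1 heart left out (35 without 3 dpi heart 3, 1 without 7 dpi heart 2). Day 14 against day 3 gave 2 with no filter, 18 with 3 equal runs, 14 with sections from 25%, 178 with thinning, 42 and 102 with limma-trend, and 0 to 148 (148 without 3 dpi heart 3, 11 without 7 dpi heart 1, 16 without 7 dpi heart 2, 13 without 14 dpi heart 2, 0 without 3 dpi heart 2). Day 14 against day 7 gave 1 with no filter, 10 with 3 equal runs, 9 with sections from 25%, 0 with thinning, 17 with columns 1 to 48, 0 and 0 with limma-trend, and 0 to 33 (33 without 7 dpi heart 1, 1 without 14 dpi heart 3, 0 without any 3 dpi heart, 7 dpi hearts 2 or 3 or 14 dpi hearts 1 or 2).

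The hearts share only a number: same-number hearts correlated at 0.0137 (border) and 0.175 (injury) in mouse and from -0.229 to 0.261 (middle) and -0.0902 to 0.131 (first) in zebrafish, over 0.1 in 3 and 1 of 9 pairs. With a replicate block, day 14 against day 7 gave 1 gene in the mouse border and 19 in the injury segment. The replicate block gave 10 genes in the zebrafish middle segment, day 7 against day 3, and in the first segment 4 for day 7 against day 3 and 49 for day 14 against day 3.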

Other observations

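The reading of a pseudogene of Hmga2 was chosen after its values were seen. The pseudogene Hmga2-ps1 had 6.10 CPM over the 5 mouse hearts, with a log2 fold change of 1.45 ± 0.33 (SE; limma adjusted p = 0.00118) in the injury segment, positive in 4 of 5 hearts, and 0.52 ± 0.31 (adjusted p = 0.257) in the border. Hmga2 itself had 5.86 CPM, and no test separated the reads of the gene from those of the pseudogene.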
